A study of Mus musculus with 6 samples.

How the data were processed

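Ezh2, the methyltransferase subunit of the Polycomb repressive complex that methylates histone H3, was mapped by chromatin immunoprecipitation and promoter tiling arrays in 6 samples of mouse embryonic stem (ES) cells. Each array had 2 channels. Per the labels, immunoprecipitated DNA carried Cy5 and input DNA of the same cells carried Cy3 on all 6 arrays, so no array had its dyes swapped. The groups, taken from the labels, were R1 ES cells with control siRNA (1 array), R1 ES cells with Brca1 siRNA (1 array), AB2.2 ES cells with wild-type Brca1 (2 arrays) and PL2F8 ES cells deficient in Brca1 (2 arrays). Nothing in the labels says that the duplicates came from separate cultures, so the p-values here measure only the spread between these arrays, which may be technical.

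The deposited table of the authors gives 1 log2 ratio per probe and array for 714900 probes. The authors computed ChIP over input after normalization, per the labels; the normalization method, software and genome build are not given in the sources used here. Its medians lay between 0.02 and 0.04, so the arrays had been centred near 0 before deposit, by a method that remains unknown. Scale and direction were settled against the peak files. Per the file headers, the score of a peak is the log2 ratio of the fourth highest probe in it, and this score correlated with the fourth highest value of the table inside the same peak at r between 0.97 and 0.99. The ratio of score to table value had a median of 0.98 on every array. The authors' peak lists were deposited for each array separately and give each peak a false discovery rate as a fraction, at most 0.198, and the nearest transcription start with a gene symbol. The peak caller is not given in the sources used here. Coordinates are printed as the files give them. The gene table supplied was of assembly GRCm38, and 10.2% of the transcription starts in the peak lists lay within 2000 bp of the gene in that table, so its coordinates were not used.

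Each array was centred on its median over all probes, with no loess or quantile step. Probes were joined into regions, split where neighbours started 1000 bp or more apart; longer runs were cut into equal parts of at most 5000 bp, and a region needed at least 5 probes. A region is printed from the start of its first probe to the start of its last. This gave 20029 regions with a median of 37 probes and 3917 bp, and 496 probes stayed outside. The value of a region was the mean of its probes. A region was named by a gene whose transcription start in the peak lists lay in it or, failing that, within 5000 bp. Where a gene had starts in several regions, the region with the highest mean signal over the 6 arrays stood for it in the lists. Only genes that the authors listed beside a peak of at least 1 of the 6 arrays have a name here, 9614 genes in 9569 regions, so a list of genes that Ezh2 rarely binds is represented by its bound members. Brca1 and Ezh2 themselves have no named region. The arrays measure binding at DNA, so they cannot check the loss of Brca1 in any sample.

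AB2.2 and PL2F8 were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all regions, threshold 0.05). Standard errors (SE) are the moderated ones of this fit, which draw the spread of a region towards that of all regions. At a single region they can be smaller or larger than its own arrays would give. The 15 gene lists and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at its preset correlation of 0.01, which compares a list with the other named genes, and with fry, which tests whether a list moves one way on balance without reference to other genes. The mean of a list per array was compared by an exact permutation test, which cannot go below p = 0.333 with 2 arrays against 2. The R1 arrays have 1 array per group and no test; a list was placed among 10000 random lists of the same size, matched on mean log2 ratio. Correlations are across regions, which are not independent replicates. Peaks were compared by overlap of at least 1 bp. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The R1 differences at regions that differed by at least 0.5 in PL2F8, and at regions called higher with a listed peak, were set beside random draws of as many regions, matched in 20 bins of mean R1 signal; this baseline was added after the results had been seen.

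The genes named are the 12 regions with the largest rise and the 12 with the largest fall in PL2F8 among those past the threshold whose PL2F8 arrays both lay on the same side of both AB2.2 arrays; the 10 highest and 10 lowest R1 differences at regions with a listed peak in an R1 array; and, of each list, the 2 members with the highest and the 2 with the lowest PL2F8 minus AB2.2. Each gene counts once. Some genes that this rule names are not reported here. Cdkn2a and the Hox genes could be named in any case.

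The region test was tried on simulated data with the real spread, 20029 regions and 200 of them changed. It recovered 54% of changes of 0.5 and 2% of changes of 0.25 on the log2 scale, with 0 false calls. The simulated noise was independent between regions, and few regions changed. In the real comparison 68.3% of regions were called, so these rates do not describe the real calls. For the R1 comparison, 200 random lists of 39 genes out of 9614 with shuffled values had a median percentile of 48.95, and 7% of them lay outside the central 95%. With 0.2 added to their members, 100% lay above the 97.5th percentile. Shuffling removes any variation that the genes of a real list share. The check therefore cannot show how far such variation makes the percentiles of real lists more extreme. Alternatives covered the centring and scaling, the summary of probes, the regions, the fit, the replicate number as a block, the number series in the array names, each array left out, and stricter peaks. The number of arrays limits the precision of every comparison.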

Results

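Ezh2 occupancy of promoters was measured on 6 promoter tiling arrays, each hybridised with Ezh2 immunoprecipitate against input DNA of the same mouse ES cells. The R1 line had been transfected with control siRNA or with siRNA against Brca1, the breast cancer gene whose product acts in DNA repair, and was harvested 48 hours later; each condition had 1 array. The AB2.2 line carries wild-type Brca1 and the PL2F8 line is deficient in it, and each had 2 arrays. The study asked how loss of Brca1 affects the places to which Ezh2 is targeted. Values are log2 ratios of ChIP over input, averaged over the probes of a region and centred on each array's median, and a difference of 1 on this scale is a doubling. Region values of the duplicates correlated at r = 0.997 for PL2F8 and 0.987 for AB2.2, and the standard deviation of their differences was 0.06 and 0.10.

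Among the gene lists, the strongest Ezh2 signal on every array lay at genes of developmental regulators. The 39 Hox genes, which pattern the body axis, had a mean log2 ratio of 1.90 ± 0.09 (SD, n = 2) in AB2.2, 2.14 ± 0.07 (SD, n = 2) in PL2F8, 2.49 on the R1 control array and 2.42 on the R1 Brca1 siRNA array. The 99 other homeobox, paired box and LIM genes had means of 2.05 ± 0.11, 2.42 ± 0.08, 2.49 and 2.43 in the same order. The control groups lay near the array median: 130 olfactory receptor genes had means of 0.12 in AB2.2, 0.11 in PL2F8, 0.09 on the R1 control array and 0.08 on the R1 Brca1 siRNA array, and 11 ribosomal protein genes had -0.15, 0.09, -0.03 and -0.20. Around the starts of the 291 genes in the 5 developmental lists, the signal was highest downstream of the start. From 250 to 500 bp it reached 3.02 and 2.65 on the AB2.2 arrays, 3.48 and 3.32 on the PL2F8 arrays, 3.10 on the R1 control array and 3.04 on the R1 Brca1 siRNA array.

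**Figure D1:**
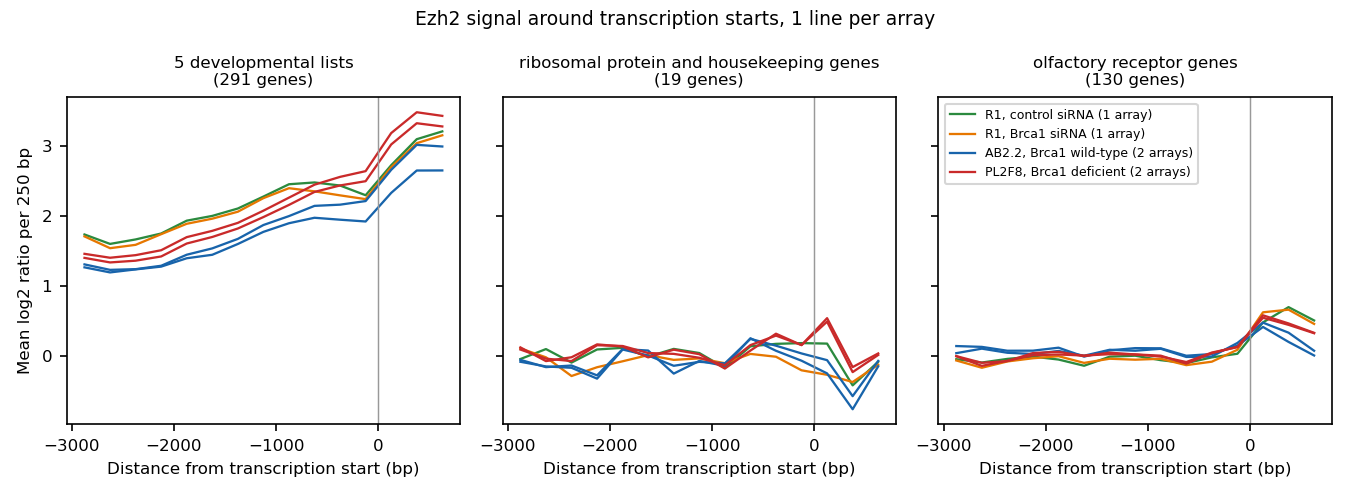
Mean log2 ratio of Ezh2 ChIP over input per 250 bp (vertical axis) against distance from the transcription start in bp (horizontal axis), 1 line per array, for 291 developmental genes, 19 ribosomal protein and housekeeping genes and 130 olfactory receptor genes. Downstream of the start of the developmental genes, both PL2F8 lines lie above the other 4, and between 250 and 500 bp the PL2F8 mean exceeds the AB2.2 mean by 0.57. A difference in this direction is not confined to developmental genes. In the same bin it is 0.47 at ribosomal protein and housekeeping genes, whose signal there is below the median of every array. At olfactory receptor genes it is 0.19. Between 0 and 250 bp the 3 groups have 0.61, 0.67 and 0.12. They part more in other bins, with 0.50, 0.17 and -0.04 between -250 and 0 bp. Between 500 and 750 bp they have 0.53, 0.13 and 0.29.

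The authors listed 6257 peaks on the R1 control array and 6432 on the R1 Brca1 siRNA array, 5482 and 4864 on the AB2.2 arrays, and 6386 and 6273 on the PL2F8 arrays. All of the 99 homeobox, paired box and LIM genes had a listed peak on both PL2F8 arrays and 98 of them on each other array, and 38 of the 39 Hox genes had one on each AB2.2 and PL2F8 array. Pluripotency genes differed: of 18 measured, 12 had a listed peak on each AB2.2 array, 7 on each PL2F8 array, 12 on the R1 control array and 13 on the R1 Brca1 siRNA array. Of 28 germline genes, 10 had one on each AB2.2 array, 19 and 20 on the PL2F8 arrays, 20 on the R1 control array and 21 on the R1 Brca1 siRNA array. In all, 4033 genes had a listed peak on all 4 AB2.2 and PL2F8 arrays, 1507 on both PL2F8 arrays and neither AB2.2 array, and 528 on both AB2.2 arrays and neither PL2F8 array. Counting only peaks with a false discovery rate at or under 0.05, these numbers were 2417, 805 and 467. Many of these genes differed little in signal: the median PL2F8 minus AB2.2 was 0.35 for the 1507 genes and -0.18 for the 528 genes. It was 0.27 for the 4033 genes with a peak on all 4 arrays. Of the 1507 genes, 651 (43.2%) also had a listed peak on the R1 control array, and of the 528 genes 152 (28.8%) did. On that array 6416 genes had a listed peak, where 9614 genes have a name here. Between duplicates, 90.3% of the peaks of PL2F8 replicate 1 overlapped a peak of replicate 2, and 78.4% of those of AB2.2 replicate 1 overlapped one of replicate 2. Between lines, 61.6% of the peaks of PL2F8 replicate 1 overlapped a peak of AB2.2 replicate 1, and 71.9% the other way. Of the peaks on the R1 Brca1 siRNA array, 69.0% overlapped a peak on the control array. Peaks were listed for each array separately, and no test was made on the lists.

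The comparison of AB2.2 with PL2F8 asked which regions carry more or less Ezh2 in cells deficient in Brca1. The largest rise was at Hspb3, a small heat shock protein gene of muscle (chromosome 13, 114453069 to 114454469), from 0.36 in AB2.2 to 2.26 in PL2F8. That is a difference of 1.90 ± 0.06 (SE), with a limma adjusted p of 2.3e-05. Next among regions with a named gene came Tpp1, a lysosomal peptidase gene (1.46 ± 0.06), Lamb2, a laminin gene of basement membranes (1.39 ± 0.04), Zfp521, a zinc finger factor gene (1.35 ± 0.11), and Osgin1 (1.34 ± 0.07). E330016A19Rik (1.24), Shank2, which encodes a scaffold of the synapse (1.23), Paqr7, a membrane progestin receptor gene (1.22), Hr, the hairless corepressor gene (1.21), Tmem185b (1.20), Nt5dc2 (1.20) and Rgs19, a regulator of G protein signalling (1.20), complete the 12 largest rises at named genes. The R1 control array also had more signal than the AB2.2 mean at each of these 12 regions, for example 1.72 at Hspb3 and 1.66 at Zfp521, where AB2.2 had 0.54.

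The largest falls were smaller. Exosc5, a subunit gene of the RNA exosome (chromosome 7, 26444018 to 26446954), fell by 1.03 ± 0.05 (SE) from 0.61 in AB2.2 to -0.42 in PL2F8, with a limma adjusted p of 2.7e-05. Olfr168 fell by 0.99, Mrrf, the mitochondrial ribosome recycling factor gene, by 0.97, the pseudogene Cyp2j7-ps by 0.94, and Grinl1a by 0.92. Rhoc, a small GTPase gene, Cst9, a cystatin gene, Crip1, Chst3, a chondroitin sulfotransferase gene, Rln1, the relaxin gene, and Olfr1501 fell by 0.90, 0.90, 0.90, 0.86, 0.85 and 0.85. The AB2.2 means of these named regions ran from 0.42 at Mrrf to 0.96 at Crip1. The R1 control array had less signal than the AB2.2 mean at each of these named regions except Crip1, where it had 1.21. It had -0.51 at Exosc5, -0.30 at Mrrf and -0.30 at Cyp2j7-ps.

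Over all 20029 regions, 9618 were higher and 4055 lower in PL2F8 (limma, adjusted p under 0.05), of which 1971 were higher and 174 lower by at least 0.5. Among the 7700 regions with a listed peak on an AB2.2 or PL2F8 array, 4990 (64.8%) were higher and 889 (11.5%) lower, with a median difference of 0.24. Among the 12329 others, 4628 were higher and 3166 lower, with a median of 0.04. The median over all regions was 0.11, and it was -0.01 after quantile normalization. That scaling turned the split from 9618 higher and 4055 lower to 6529 higher and 7187 lower, so the direction of small differences depended on the scaling. The count of large differences depended on it too: 752 regions were higher and 474 lower by at least 0.5 after quantile normalization. With the median of probes these counts were 1587 and 70, and with the highest running mean of 5 probes 6120 and 2288. Of the 1971 rises of at least 0.5, 1970 stayed higher past the test threshold after quantile normalization, whatever their size there, and so did all 174 falls of that size in their direction. The count of lower regions fell to 2333 without PL2F8 replicate 1 and to 2689 without PL2F8 replicate 2.

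**Figure D2:**
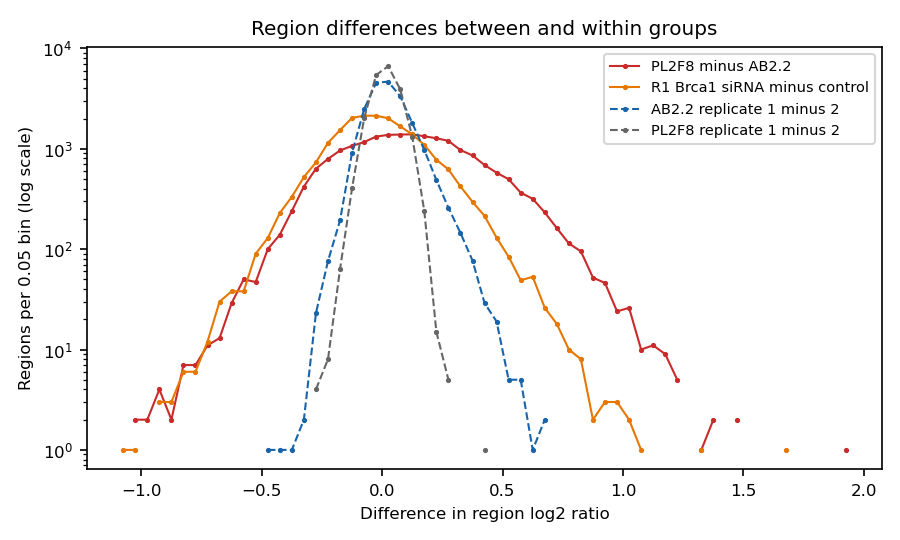
Number of regions per 0.05 bin, on a log scale, against the difference in region log2 ratio between groups (solid lines) and between duplicates (dashed lines). The difference of PL2F8 and AB2.2 spreads furthest to the right, with 1971 regions called higher by 0.5 or more, while 13 regions of the AB2.2 duplicates and 0 of the PL2F8 duplicates differ by that much.

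Of 291 genes in the 5 developmental lists, 215 were higher in PL2F8, 19 lower and 57 not called, with a median difference of 0.34, or 1.26-fold. All named genes had a median of 0.23, and none of the 5 lists was called higher than other genes by camera or higher by fry. After quantile normalization 148 were higher and 61 lower, with a median of 0.12. The median of the R1 control array minus the AB2.2 mean at the same genes was 0.43. Of the 58 mesoderm and endoderm regulators, 48 rose and 4 fell, with a median of 0.40. The kidney and gonad factor gene Wt1 rose by 1.06 ± 0.06 (SE), from 1.61 to 2.67, and Foxa1, an endoderm pioneer factor gene, by 1.02 ± 0.07, while Tbx3 fell by 0.37 and Foxq1 by 0.30. Of the 99 homeobox, paired box and LIM genes, 75 rose and 3 fell, with a median of 0.38. Tlx3 and the forebrain gene Otx1 rose by 1.01 and 0.95, and the eye gene Vax2 fell by 0.39. Of 36 neural regulators, 27 rose and 3 fell (median 0.34), with Bhlhe22 at 1.03 and Insm1 at 0.72 against Zic5 at -0.43 and Ebf1 at -0.30. Of 59 signalling ligands and receptors, 38 rose and 4 fell (median 0.24; 0.01 after quantile normalization, with 22 higher and 20 lower). Sfrp2 and Wnt7a, both of the Wnt pathway, rose by 0.84 and 0.79, and Fgf11 and the Notch ligand gene Dll1 fell by 0.54 and 0.46.

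Of the 39 Hox genes, 27 were higher and 5 lower in PL2F8, with a median of 0.25, but this direction depends on the scaling: after quantile normalization 17 were higher and 10 lower, with a median of 0.01 and a mean of -0.00433. Hoxd9 rose by 0.67 ± 0.08 (SE), from 1.95 to 2.61, and Hoxa9 by 0.59 ± 0.06. Hoxc4 fell by 0.37 ± 0.08 and Hoxc5 by 0.36 ± 0.06. The 5 Hox genes that fell were Hoxa4 and 4 genes of the Hoxc cluster, Hoxc4, Hoxc5, Hoxc12 and Hoxc13. In the same cluster Hoxc10 rose by 0.40, Hoxc6 by 0.36 and Hoxc9 by 0.31.

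**Figure D3:**
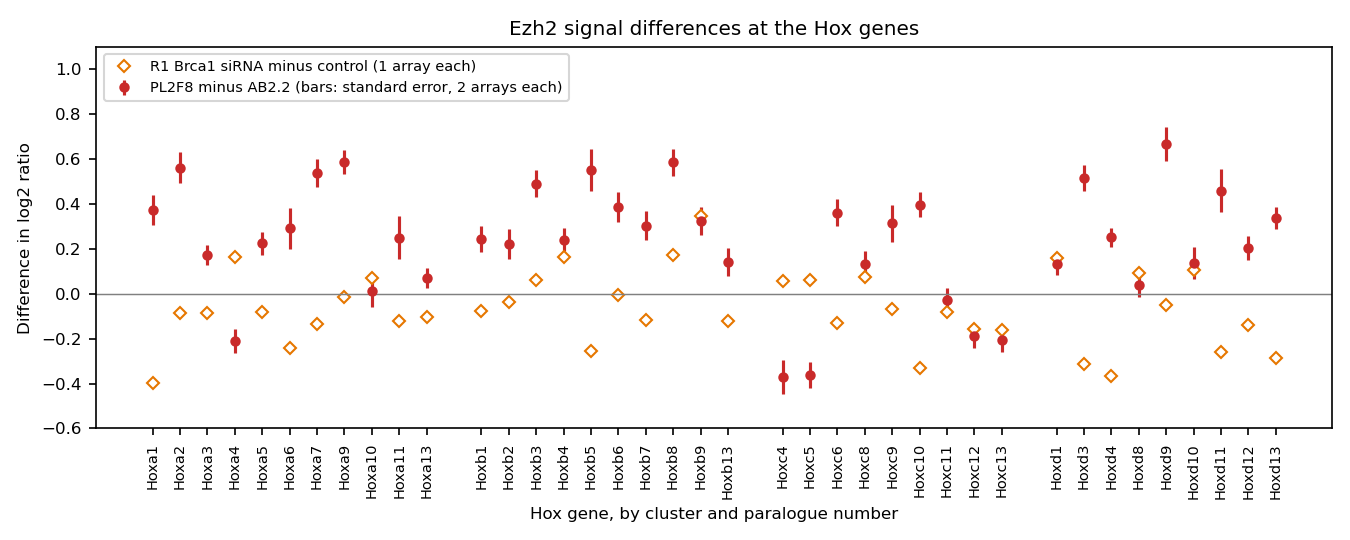
Difference in log2 ratio (vertical axis) at each of the 39 Hox genes (horizontal axis, by cluster). Filled circles with moderated standard errors show PL2F8 minus AB2.2 (2 arrays each). Open diamonds show R1 Brca1 siRNA minus control (1 array each). Hoxd9 is highest at 0.67 and Hoxc4 lowest at -0.37 among the filled circles, some of which change sign under quantile normalization.

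Pluripotency genes did not share this rise. Of 18 measured, 6 rose, 7 fell and 5 were not called, with a median of -0.09. Pou5f1, the gene of the core pluripotency factor Oct4, fell by 0.57 ± 0.05 (SE) from -0.01 to -0.57, and Fgf4 fell by 0.44, from 0.21 to -0.23. As region means both started near the array median, so these falls do not show a loss from strong Ezh2 signal. Esrrb and the DNA methyltransferase gene Dnmt3b rose by 0.64 and 0.63. Relative to the other named genes, whose median was 0.23, the list was lower by 0.31 (camera, adjusted p = 6.8e-04; adjusted p = 0.0541 with the median of probes, 0.321 with the highest running mean of 5 probes and 0.978 with an estimated correlation). Of 130 olfactory receptor genes, 45 rose and 52 fell, with a median of -0.09 and a mean of -0.01, led by Olfr282 (1.16) and Olfr1411 (1.04) and closed by Olfr168 and Olfr1501, above. The list was lower than other genes by 0.32 (camera, adjusted p = 6.1e-11; adjusted p = 0.135 with an estimated correlation). Its signal in PL2F8 differed from AB2.2 by -0.09 between -3000 and -2750 bp from the start, and by 0.19 between 250 and 500 bp. No list was called higher than the other named genes: by camera the homeobox list and the mesoderm and endoderm list had adjusted p = 0.0718 each, both under 0.05 before adjustment, and the remaining lists had adjusted p between 0.318 and 0.889. Leaving out AB2.2 replicate 1 made 4 lists called higher, leaving out AB2.2 replicate 2 made it 1, and leaving out PL2F8 replicate 2 made it 2. The median of probes made it 3, and scaling to the same median absolute deviation and centring on regions without a listed peak made it 2 each. With an estimated correlation no list of the 15 was called, and each list but the olfactory receptors had adjusted p = 0.978.

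The smaller lists mostly followed the general rise. Of 29 imprinted genes, 21 rose and 1 fell (median 0.38), with Kcnk9, a potassium channel gene, up by 1.11 and Gnas by 0.95; Trappc9 fell by 0.23, and Cdkn1c had a difference of -0.10. Of 14 cell cycle inhibitors, 9 rose and 2 fell (median 0.38): Rassf1 and Lats2, both of the Hippo pathway, rose by 0.76 each, Gadd45b fell by 0.59 and Cdkn1b by 0.20. Cdkn2a, the gene of the Ink4a and Arf tumour suppressors, has a pair of regions on chromosome 4. The region at 88927300 fell by 0.50 ± 0.04 (SE), and the one at 88939726 had a difference of -0.04 with an adjusted p of 0.669. By the rule for lists, only the region at 88939726, with the higher mean signal, stands for the gene. Of 21 Polycomb subunit genes, 13 rose and 3 fell (median 0.24; 9 higher and 8 lower after quantile normalization), with Pcgf2 up by 0.76, Kdm2b up by 0.52, Suz12 down to 0.03 from 0.28 and Phf19 down to 1.03 from 1.27. Of 28 germline genes, 20 rose and 2 fell (median 0.21); the meiotic endonuclease gene Spo11 rose by 0.51 and Tdrd6 by 0.50, and Ddx4 fell by 0.22 and Nanos2 by 0.20. Of 14 fibroblast feeder markers, 10 rose and 3 fell (median 0.34), with Col1a1 up by 0.81 and Pdgfra by 0.72, and Fn1 and Thy1 down by 0.15 and 0.13.

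Genes of the control lists were called as well. As lists, ribosomal protein genes passed fry alone, and olfactory receptor genes, above, passed camera at its preset correlation alone. Of 11 ribosomal protein genes, 9 rose and 2 fell (median 0.26), with Rpl7 up by 0.64, Rpl28 by 0.52, Rpl34 down by 0.31 and Rplp0 down by 0.11. Of 12 DNA repair genes, 6 rose and 3 fell (median 0.12), among them Xrcc1 at 0.54 and Uimc1 at 0.32, and Wrn at -0.17; after quantile normalization 4 repair genes were higher and 5 lower, with a median of 0.03 and a mean of -0.00888. Of 8 housekeeping genes, 2 rose, Ldha by 0.92 and Polr2a by 0.16, and 6 were not called, with Actg1 at -0.14 and Ywhaz at -0.01. Their median of 0.04 became -0.09 after quantile normalization. Counts adjusted over the list alone were 32 Hox, 78 homeobox, 30 neural, 52 mesoderm and endoderm, 43 signalling, 13 pluripotency, 16 Polycomb, 9 repair, 11 cell cycle, 22 imprinted, 23 germline, 11 ribosomal, 2 housekeeping, 102 olfactory receptor and 13 feeder genes. The median lay above that of other genes but camera's direction was down for the signalling, Polycomb and cell cycle lists, and the reverse held for germline genes. By fry, which takes no account of other genes, ribosomal protein genes alone passed the threshold (adjusted p = 0.0261). The other lists had adjusted p between 0.0659 and 0.237, which with 2 arrays per line does not show that they did not move one way.

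**Figure D4:**
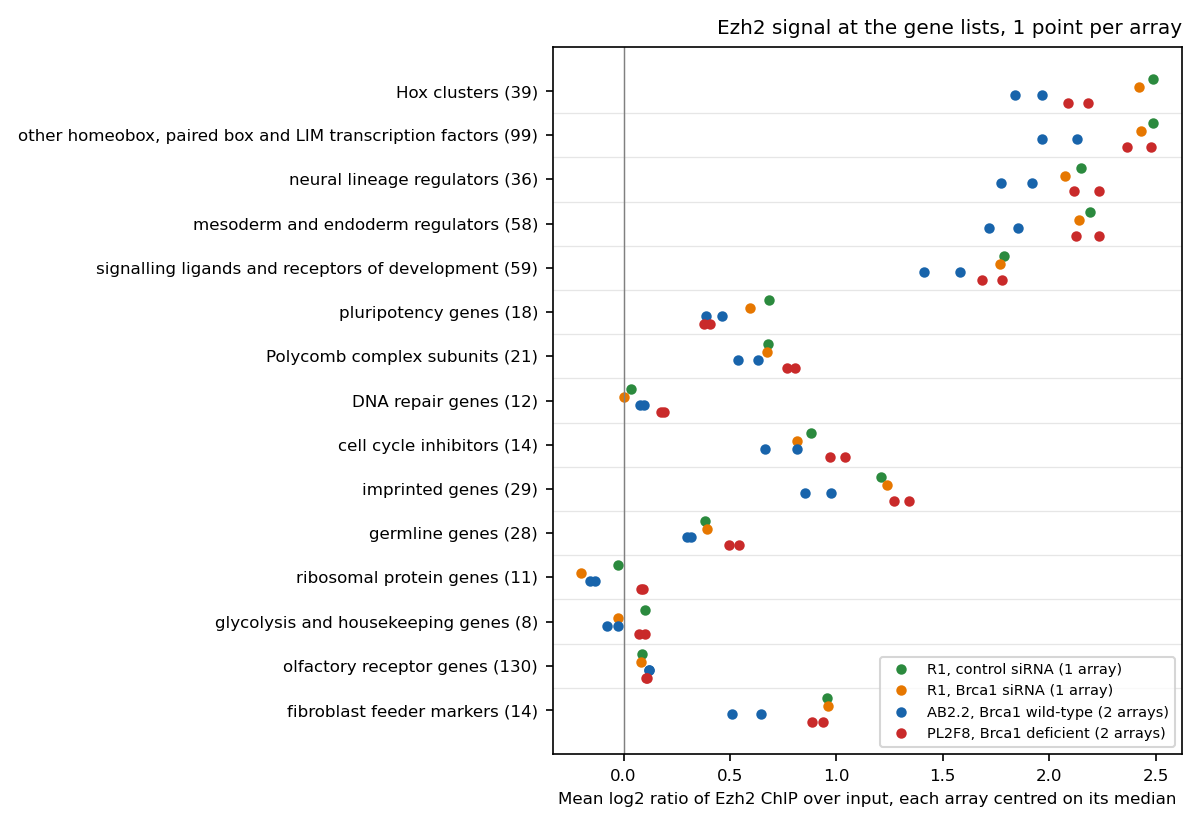
Mean log2 ratio of Ezh2 ChIP over input (horizontal axis) for each of the 15 gene lists (vertical axis, number of genes in parentheses), 1 point per array in the colour of its group. At the mesoderm and endoderm regulators, for example, AB2.2 has 1.85 and 1.72, PL2F8 2.23 and 2.13, and the R1 arrays 2.19 and 2.14.

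Per array, the mean of every list except pluripotency and olfactory receptor genes was higher on both PL2F8 arrays than on both AB2.2 arrays, although after quantile normalization the mean difference turned below 0 for Hox, DNA repair and housekeeping genes. The olfactory receptor mean was lower on both. The exact permutation test gave p = 0.333, the smallest that 2 arrays against 2 allow, for all lists except pluripotency genes, with p = 0.667. For the mesoderm and endoderm list the difference of 0.40 exceeded the SDs of the duplicates, 0.10 and 0.07. Across regions the R1 control array correlated at r = 0.931 and 0.933 with the PL2F8 arrays and at 0.878 and 0.851 with the AB2.2 arrays. Within the number series of the array names that holds both AB2.2 arrays and PL2F8 replicate 2, the median over the 291 developmental genes was 0.28; the other series holds no AB2.2 array.

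The R1 pair asked whether short-term depletion of Brca1 goes with like differences. With 1 array per group these differences have no replicate check. Of 7505 regions with a listed peak on an R1 array, 202 were higher and 129 lower by at least 0.5 with Brca1 siRNA, and the median difference was 0.02. These counts were 133 and 134 after scaling to the same median absolute deviation, 411 and 167 with the median of probes, and 1490 and 1464 with the highest running mean of 5 probes. Among such regions with a named gene, Galr3, a galanin receptor gene (chromosome 15, 78869139 to 78873039), was highest, with -0.21 on the control array and 0.87 with Brca1 siRNA, a difference of 1.08. Without a named gene, 2 short regions of 5 probes each differed by more. Kcnj12, a potassium channel gene, was higher by 1.03, Sigirr, a regulator of interleukin receptor signalling, by 1.02, Btnl7 by 0.98, Upk2, a uroplakin gene, by 0.95, Tbc1d16 by 0.95, Gpr97 by 0.91, Lpcat2 by 0.87, Arhgap27 by 0.85 and Nt5dc2 by 0.84. The lowest was Catsper3, a sperm cation channel gene (chromosome 13, 55885098 to 55886635), with 1.00 on the control array and -0.09 with Brca1 siRNA, a difference of -1.09. Next among named genes were the region shared by Adat3 and Scamp4 (-1.04), Dhrs1 (-0.95), Itpkc (-0.94), Elmo2 (-0.88), Timm13 (-0.84), Mbd1, a methyl-CpG binding protein gene (-0.83), Fam92b (-0.80), Kcnj2 (-0.78) and Nhs (-0.76). The standard deviation of the R1 difference over all regions was 0.21, against 0.06 and 0.10 between the duplicates of the other lines.

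Developmental genes were not higher with Brca1 siRNA. Of the 291, 116 had higher and 175 lower values than on the control array, with a median of -0.07, while the AB2.2 and the PL2F8 duplicates differed by 0.14 and 0.11 at the same genes. After scaling to the same median absolute deviation the R1 median was -0.19, and the duplicates differed by 0.07 and -0.03. After quantile normalization the R1 median was -0.02. The mesoderm and endoderm list had a median of -0.11, at the 0.62 percentile of random lists matched on signal, and ribosomal protein genes had -0.20, at the 1.21 percentile, with Rplp0 at -0.46. Hox genes had a median of -0.08 (percentile 15.6) and homeobox genes -0.04 (39.8). Neural regulators had -0.07 (15.6), signalling genes -0.0015 (39.2), pluripotency genes -0.11 (3.04) with Pou5f1 at -0.55, and housekeeping genes -0.14 (7.57) with Ldha at -0.59. The remaining lists lay between the percentiles of 29.6, for feeder markers, and 85.4, for imprinted genes: olfactory receptor genes at 45.2, Polycomb genes at 47.9, DNA repair genes at 74.2, cell cycle inhibitors at 39.2 and germline genes at 38.7.

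Across the 20029 regions, PL2F8 minus AB2.2 correlated with R1 Brca1 siRNA minus control at Pearson's r = 0.15 and Spearman's rho = 0.16. The sign was the same in 54.3% of regions. In the highest twentieth of regions by mean signal it was the same in 47.6%, or 54.9% about each difference's own median. These differences share no array. Both varied with mean signal, with medians of 0.00143 and -0.0457 in bin 9 of 20, 0.300 and 0.0283 in bin 19, and 0.361 and -0.0149 in bin 20. How much of the correlation goes with signal was not tested. In the 1971 regions higher by at least 0.5 in PL2F8, 1180 (59.9%) were also higher with Brca1 siRNA, with a median of 0.06. Random regions matched on R1 signal gave 50.8% and a median of 0.00425, with 95% of draws between 48.7% and 53.1%; over all regions, most of which have little signal, 44.4% were higher. In the 174 regions lower by that much, 106 (60.9%) were lower with Brca1 siRNA, with a median of -0.04, which matched random regions also gave, at 57.5% (51.1% to 64.4%) and a median of -0.0351. Among the named genes, Nt5dc2 was among the largest rises in both comparisons, by 1.20 and 0.84, and Rgs19 had 1.20 and 0.63. Hspb3 and Tpp1 had R1 differences of -0.25 and -0.22. Of the 10 named regions highest with Brca1 siRNA, 7 rose and 1 fell in PL2F8, and of the 10 lowest likewise 7 rose and 1 fell, close to the 64.8% of regions with a listed peak that were higher in PL2F8 in general, so these regions do not tell whether both systems go the same way. Galr3 and Tbc1d16, higher with siRNA, rose by 0.76 and 0.91 and Kcnj12 fell by 0.36; Elmo2 and Mbd1, lower with siRNA, rose by 0.62 and 0.47 and Catsper3 fell by 0.38.

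**Figure D5:**
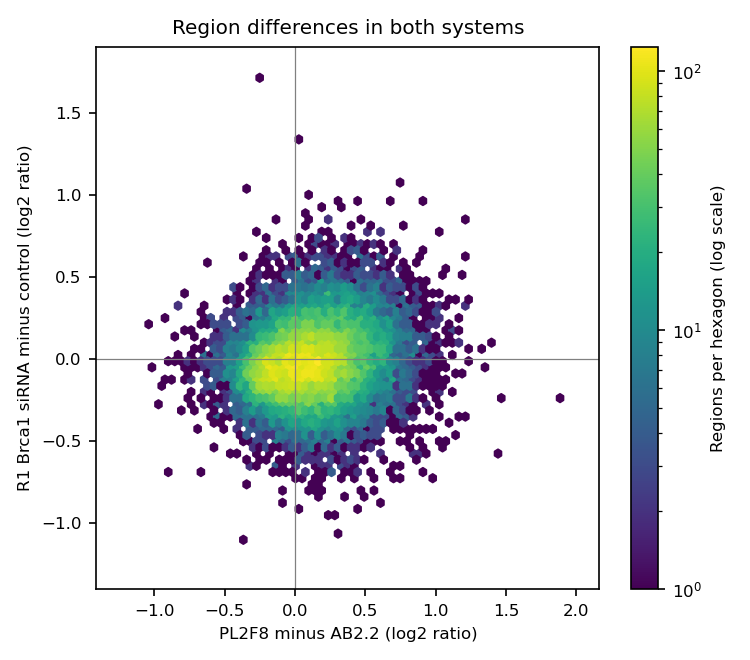
R1 Brca1 siRNA minus control (vertical axis, log2 ratio, 1 array each) against PL2F8 minus AB2.2 (horizontal axis, log2 ratio, 2 arrays each), coloured by the number of regions per hexagon on a log scale. The cloud of 20029 regions has r = 0.15 and is shifted to the right, with a median of 0.11 on the horizontal axis and -0.03 on the vertical.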

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

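The explanations weighed here were tested only after the results had been seen. For 10 gene lists the mean Ezh2 signal was higher on both PL2F8 arrays than on both AB2.2 arrays, and lower on the R1 Brca1 siRNA array than on its control. For 3 of these lists the R1 median was not lower: it was 0.03 for DNA repair, 0.01 for Polycomb and 0.00148 for cell cycle genes. The difference between PL2F8 and AB2.2 exceeded that between the R1 arrays by 0.45 for mesoderm and endoderm regulators, 0.43 for homeobox, paired box and LIM genes, 0.41 for ribosomal protein genes, 0.40 for neural regulators and 0.33 for cell cycle inhibitors. It did so by 0.30 for Hox genes, 0.27 for housekeeping genes, 0.26 for signalling genes, 0.21 for Polycomb genes and 0.13 for DNA repair genes. With 1 R1 array per condition this difference was not tested, and after quantile normalization the PL2F8 mean fell below that of AB2.2 for Hox, DNA repair and housekeeping genes.

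The first pattern is the higher signal in PL2F8 over regions with a listed peak, where the median was 0.24. Within the series of array names that holds 3 of the 4 arrays the median was 0.22, which argues against the number series as the cause. After quantile normalization the median was 0.0811, but that step forces the arrays to 1 distribution, so a stronger enrichment on the PL2F8 arrays and a broad gain of Ezh2 cannot be told apart. At regions higher in PL2F8 than in AB2.2 replicate 2, the R1 control array exceeded AB2.2 replicate 1 by a median of 0.20; AB2.2 cells are in both differences, and 3 equally different lines would give 0.19, so this cannot tell whether AB2.2 stands apart. At the 4990 regions called higher in PL2F8, Brca1 siRNA minus control in R1 had a median of 0.0197, against 0.0138 at random regions of like signal, which cannot decide on a loss of Brca1, since the extent of the knockdown is not given and each condition has 1 array.

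The second pattern is the set of regions that differed by at least 0.5. The 1971 rises kept a median of 0.46 after quantile normalization, against 0.62 before, which argues against strength of enrichment as the whole cause, although only 752 regions were then higher by 0.5. The R1 control array exceeded AB2.2 replicate 1 by a median of 0.39 at rises defined with AB2.2 replicate 2, and differed from it by -0.51 at falls defined that way, where 3 equally different lines would give 0.32 and -0.30. Brca1 siRNA minus control had medians of 0.056 at the rises and -0.0406 at the falls, far smaller than the differences between lines; random regions of like signal gave 0.00425 and -0.0351, so the value at the falls is no more than other regions show. A loss of Brca1 and other differences between the lines cannot be told apart here, because line and Brca1 status coincide and AB2.2 cells are in both comparisons.

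The third pattern is the lower signal of the 291 developmental genes with Brca1 siRNA in R1, with a median of -0.07. The duplicates of PL2F8 differed by a median of 0.11 at these genes, the smaller of the differences within AB2.2 and PL2F8. After scaling to the same median absolute deviation the R1 median was -0.19 and the duplicates differed by 0.07 and -0.03, while after quantile normalization it was -0.02. Spread between arrays of the same cells and an effect of Brca1 siRNA therefore cannot be told apart.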

How the results depend on the processing

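Alternatives were planned before the data were examined, except centring on regions without a listed peak, the array's own tiled regions, probes matched once and the highest twentieth of regions, which were chosen after seeing the data. The 24 regions with the largest rises and falls in PL2F8 kept direction and side of the threshold in all 431 of their values. They had been picked as the largest differences on these same arrays, so this says little about other regions. Of the values that answer a comparison, 115 stayed as they were and 49 moved, and 1 reversed. Where no cause follows from the alternative itself, the cause was not tested.

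Quantile normalization gave 7187 regions lower in PL2F8, 752 higher by at least 0.5 and 474 lower by at least 0.5; by construction it removes a shift shared by most regions. It turned the mean difference at Hox genes to -0.00433 and left 0.15 at homeobox genes. Relative to other genes, it turned the median of the Hox list to -0.0727, of signalling genes to -0.0685 and of germline genes to 0.00197. The correlation between both systems was 0.132 under it. The median of probes gave 5754 regions higher by any amount, 1587 higher and 70 lower by at least 0.5, and 411 R1 regions higher by 0.5. It called 3 lists higher and 1 lower than other genes, and turned the relative medians of Polycomb, imprinted and ribosomal protein genes to -0.005, -0.0125 and -0.0375. The pluripotency list was no longer called under it (adjusted p = 0.0541), nor with the highest running mean of 5 probes (0.321). The highest running mean of 5 probes gave 6120 regions higher and 2288 lower by at least 0.5, and 1490 higher and 1464 lower in R1, and called 1 list lower. It turned the relative medians of Hox (-0.21), homeobox (-0.17), neural (-0.14), mesoderm and endoderm (-0.19), signalling (-0.24), Polycomb (-0.19), ribosomal protein (-0.064), feeder (-0.13) and germline genes (0.33).

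Regions with a listed peak only gave 4768 higher and 794 lower, fewer because fewer were tested, a correlation of 0.113, and relative medians of -0.00325 for signalling, -0.00557 for Polycomb and 0.0757 for germline genes. In the highest twentieth of regions the correlation was 0.0960. Scaling to the same median absolute deviation called 2 lists higher, and 133 R1 regions were higher by 0.5. Centring on regions without a listed peak called 2 lists higher. The relative median of germline genes became 0.0519 with the array's own tiles and 0.0162 with probes matched once, and that of ribosomal protein genes -0.000115 with a 500 bp gap. Fry, which compares no list with others, called 1 list higher and 0 lower, and camera with an estimated correlation called 0 lower.

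The array number series as a block, which amounts to leaving out PL2F8 replicate 1, gave 2333 regions lower and relative medians of -0.00436 for signalling and -0.0030 for Polycomb genes. Leaving out each array gave between 2333 and 4347 regions lower and between 0 and 4 lists called higher, with the lone array assumed to vary like the other group. Relative medians then ran from -0.0132 to 0.061 for Hox, -0.0489 to 0.11 for signalling, -0.0030 to 0.0716 for Polycomb, -0.0576 to 0.0256 for germline and -0.00834 to 0.0815 for ribosomal protein genes. With the replicate number as a block, 10207 regions were higher and 4487 lower, and 3 lists were called higher; same-numbered deviations correlated at 0.225 over only 2 pairs, too few to show whether the numbers pair the arrays.

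Peaks with a false discovery rate at or under 0.05 numbered 3963 on the R1 control array, 4178 with Brca1 siRNA, 3724 and 3346 for AB2.2, and 3973 and 4084 for PL2F8. At or under 0.01 they numbered 2357 and 2388 for R1, 2275 and 2107 for AB2.2, and 2460 and 2488 for PL2F8, fewer by construction. When at least 50% of a peak had to overlap, the shares were 86.3% within PL2F8, 71.7% within AB2.2, 45.4% of PL2F8 in AB2.2, 56.1% of AB2.2 in PL2F8 and 57.9% of Brca1 siRNA in control. With the rate at or under 0.05, 66.1% of PL2F8 peaks overlapped AB2.2 and 70.6% the other way. Among the remaining values, of lists and single regions, 685 stayed as they were, 26 moved, 29 reversed, 17 passed the threshold newly and 4 no longer passed it. Signal over background limits what small differences can show.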

Other observations

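Gene families and chromosomes were chosen for a look only after the data had been seen, and no explanation was tested for them. The 54 clustered protocadherin genes, which encode adhesion molecules of neurons, had a median PL2F8 minus AB2.2 of 0.09, at the 0.02 percentile of random lists matched on signal, whose median was 0.27. With Brca1 siRNA in R1 their median was -0.05, at the 1.43 percentile. Random lists are drawn from all named genes, while clustered genes lie side by side and may vary together. Both percentiles may therefore be too extreme. The 11 other protocadherin genes had medians of 0.28 in PL2F8 minus AB2.2 and -0.18 in R1, at the percentiles 27.6 and 1.74. Of the 40 forkhead factor genes, 33 were higher and 2 lower in PL2F8, with a median of 0.39 at the 95.1 percentile. The 32 keratin genes had medians of 0.29 (93.4) and, in R1, 0.11 (97.7). Other families were looked at too. In PL2F8 minus AB2.2, potassium channels lay at the 52.6 percentile, cytochromes P450 at 52.7 and zinc finger proteins at 43.9. Solute carriers lay at 91.1 and collagens at 12.8. With many families looked at, some high or low percentiles can arise without any cause. These family values were computed with median centring alone. On the X chromosome, 254 of 800 regions were higher and 258 lower in PL2F8 with a median of -0.01, while the medians of the autosomes ran from 0.05 to 0.19. The 14 regions of the Y chromosome had a median of -0.13, with 1 higher and 7 lower. With Brca1 siRNA in R1 the X chromosome had a median of -0.07, the lowest of the chromosomes. Chromosomes were not matched on signal.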
